A study of Bos taurus with 16 samples.

How the data were processed

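Oocytes were taken from slaughterhouse ovaries, stripped of cumulus cells, stained with Hoechst and sorted into GV0, GV1, GV2 and GV3 by the condensation of their chromatin, per the labels' protocols. RNA of oocyte pools was extracted with a PicoPure kit, amplified to antisense RNA with RiboAmp HS and labelled chemically with Cy3 or Cy5, per the labels' protocols. The deposited scanner files hold the mean intensity of each spot and of its local background at 532 nm (Cy3) and 635 nm (Cy5), with nothing subtracted or normalised, per the file headers. The software that measured the images is not given in the sources used here. The series also has a set of the authors' processed values. Their scale and direction are not stated. From the values alone, these deposited values were read as log2 of Cy5 over Cy3, background-subtracted and not turned for the dye. They were set against the scanner values of the same array, processed here with background subtraction (correlation 0.891 to 0.976, slope 0.794 to 0.947, median absolute difference 0.015 to 0.0247). Scanner values without subtraction were not compared in this way, so the background subtraction of the deposited values was assumed. Column medians lay between −0.0045 and 0.0035, and 62 values were missing. Scale and centring were thus read from the values alone, and these values were used only as an alternative.

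The groups and the dye of each stage came from the labels. The series design gives 4 biological replicates and a dye swap, and the labels do not say which replicate is on which array. The p-values therefore measure the spread between these arrays, which may be partly technical. Each slide held the 4 arrays of 1 comparison, so slide and comparison cannot be told apart. The array labels end in what reads as a day, shared by the GV1 and GV2 arrays, with another day for GV3 against GV0 and another for GV3 against GV2. No term for the day could be fitted beside the comparisons, and the GV2 and GV1 difference lies within 1 day. The closure of the loop from GV0 through GV2 to GV3 was used as a check on this, though that test proved conservative. No arrays held identical values (0 pairs), correlations of turned ratios within a comparison ran from −0.129 to 0.795, and the lowest among arrays with GV0 was −0.0379.

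In R 4.3.3 with limma 3.58.1, intensities were background-corrected with normexp (offset 50) and normalised within each array by loess, with control spots at weight 0. Loess centres the ratios of an array, so every rise or fall is relative to the bulk of the probes. A change in total RNA between stages would not show. Each ratio was turned to later over earlier stage. A probe was tested where it lay above the mean plus 2 SD of the 757 control or empty spots in at least 50% of the channel measurements of a stage, since the files give no background SD. This kept 33251 of 43794 probes, 75.9%. limma was fitted to all 16 arrays with a coefficient per comparison and 1 dye effect shared by all arrays (11 residual and 2.25 prior degrees of freedom), and p-values were two-sided and adjusted by Benjamini-Hochberg at 0.05. The difference of GV2 from GV1 and the loop closure were contrasts of the same fit. Data were handled with the R packages data.table (version 1.17.8) and jsonlite 2.0.0, and figures drawn with Python 3.11.15 and matplotlib 3.10.9.

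Gene symbols came from the platform annotation. 21790 probes had 1 symbol, 0 had several and 22004 had none and are not named here. A gene was represented by its probe of highest mean intensity. Before the data were examined, the tests, the alternatives, 19 gene lists, 3 lists of markers of other cell types and the rule for named genes were fixed. The rule took (a) the 10 largest rises and 10 largest falls per comparison among genes past the threshold with the same sign on all 4 arrays, leaving out symbols that are only locus numbers, (b) up to 4 members of each list with the smallest p, and (c) a fixed set of genes whether or not they passed, of which H3F3A had 0 probes. That gave 459 values, and 307 of them, those that passed and those of part (c), were tested for single arrays standing apart. They were also recomputed in part of the settings. Only counts were taken with array weights, equal spread, stage coefficients, the replicate block, other filters on dim probes, background subtraction and the fold minimum. The text prints parts (a) and (c) and, of part (b), the 2 members of a list with the smallest p that passed, a reduction made after the values were seen, as was the choice of the 307 values for the test of single arrays. A gene printed for 1 comparison may thus have passed in others too. Lists were tested with camera at a preset correlation of 0.01, adjusted over 76 tests for the 19 lists and over 12 for the markers. The estimated correlation and fry were alternatives. 5 of the 76 tests passed with the preset correlation and 0 with the estimated one.

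The fit was tested on simulated data with 200 changed probes of 33251. For GV1 against GV0 it recovered 88.1% of 1.5-fold, 91.0% of 2-fold and 100% of 4-fold changes with 13 false calls. For GV2 against GV0 it recovered 71.6%, 95.5% and 100% with 9, for GV3 against GV0 86.6%, 92.5% and 98.5% with 11, and for GV3 against GV2 70.1%, 95.5% and 97.0% with 6. The simulated noise was independent between arrays, and its variances and shared dye effect came from this same fit. Dye effects that differ by slide and RNA shared between arrays were not simulated. The recovery and false calls thus hold for that setting and not for the real arrays. The alternatives changed the background correction, the offset, the normalisation, the filter on dim probes, the dye term, the arrays in the fit, the weights and the fold minimum, used the authors' values, added the replicate number as a block and left out each array. Chromosome positions of probes were not used here.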

Results

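Bovine oocytes at the germinal vesicle stage, in which the nucleus of the immature egg cell is still intact, were compared between 4 stages of chromatin condensation, from GV0, the least condensed, to GV3, the most condensed. RNA of oocyte pools was hybridised in pairs of stages to 16 arrays of 2 colours, 4 arrays for each of 4 comparisons. GV1, GV2 and GV3 were each set against GV0, and GV3 was also set against GV2. In every comparison the later stage was labelled with Cy5 on 2 arrays and with Cy3 on the other 2. Median spot intensities ranged from 166 to 265 in the Cy3 channel and from 151 to 206 in the Cy5 channel. Between 23.3% and 87.2% of probes lay above the control spots in Cy3, and between 29.9% and 71.3% did in Cy5, the lowest of each on an array with a raised control-spot threshold (606 and 323). The number of arrays limited the precision, and the median standard error of a log2 ratio in a direct comparison was 0.09. Of 43794 probes, 33251 were tested, and 17507 of these carried a gene symbol, for 12664 genes.

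The comparison of GV1 with GV0 asked which transcripts differed at the first step of condensation. The linker histone gene HIST1H1C was 4.48-fold higher at GV1 (log2 ratio 2.16 ± 0.18, SE, n = 4, limma adjusted p = 1.3e-05), with both of its probes past the threshold. The SD of its ratios on these 4 arrays was 0.57. NFKBIA, the inhibitor that holds NF-kappa-B in the cytoplasm, rose by 1.54 on the log2 scale, and TMPO, a lamina-associated protein of the inner nuclear membrane, rose by 1.34. SLC35F4, SLC12A2, a sodium, potassium and chloride cotransporter, and GALNT13, an enzyme of O-glycosylation, were higher by 2.07, 1.11 and 1.19. The other genes with the largest rises were CD3G (1.08), ZNF391 (1.07), EID1 (1.02) and RALYL (0.95). The largest fall was that of STAMBP, a deubiquitinase of the endosome, which was 5.96-fold lower (log2 ratio −2.58 ± 0.16, SE, n = 4, limma adjusted p = 1.9e-06). For STAMBP the SD on the 4 arrays was 0.23. PTCH1, the hedgehog receptor, had a log2 ratio of −2.47, AEBP2, a cofactor of Polycomb repressive complex, −2.41, and NEUROD1, a transcription factor of neurons, −2.40. HERPUD1, B3GNT2, CCDC85A, LRPPRC, a mitochondrial RNA-binding protein, CYP26A1, which degrades retinoic acid, and TMBIM6 had log2 ratios of −2.39, −2.31, −2.30, −2.22, −2.19 and −2.04. For PTCH1, AEBP2 and TMPO only 1 probe of the gene passed in that direction, of 3, 2 and 3 probes, and for RALYL 2 of 3. All 20 of these genes had the same sign on 4 of 4 arrays, which the rule for naming them required. The call for EID1 was lost with median centring in place of loess.

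Genes of chromatin changed in both directions at GV1, where 809 of all 12664 genes rose and 1705 fell. Of 48 histone methyltransferases and demethylases, 5 rose and 17 fell (5 and 18 adjusted over the list alone). SETD2, which trimethylates histone H3, was 4.00-fold lower (limma adjusted p = 7.9e-06, n = 4) with 3 of 3 probes past the threshold, and KDM6A, a histone H3 demethylase, fell by 0.84. Among 36 members of chromatin remodelling complexes 2 rose and 11 fell (2 and 11 adjusted over the list alone), with CHD1L at −0.93 and CHD9 at −0.54. Of 24 histone acetyltransferases and deacetylases 0 rose and 6 fell (0 and 7 adjusted over the list alone), HDAC6 at −0.67 and HDAC10 at −0.35. Of 36 members of the condensin, cohesin, topoisomerase and HMG list, 2 rose and 8 fell (2 and 10 adjusted over the list alone), among them STAG3, a cohesin subunit of meiosis, at −1.05, and CBX3, a heterochromatin protein, at −1.90 in 1 of 2 probes. Of 24 histone chaperones 2 rose and 1 fell (0 and 1 adjusted over the list alone), with the importin IPO4 at −0.93 and SET at 0.28. Among 16 genes of DNA methylation 1 rose and 2 fell (1 and 3 adjusted over the list alone), with TET2 at 0.56 and TDG at −0.23. HIST1H1C was the only one of 9 replication-dependent histone genes past the threshold, and 0 fell (1 and 0 adjusted over the list alone). Of 7 replication-independent variants 1 rose, H3F3C at 0.21, and 1 fell, H2AFZ at −1.38 (2 and 1 adjusted over the list alone). None of these lists passed camera, the smallest adjusted p among them being 0.214, for the replication-dependent histones. The call for SET was lost without replicates 2, 3 or 4 (adjusted p = 0.162 without replicate 3), that for H3F3C without replicate 4 (adjusted p = 0.0513), with median centring and on its own arrays alone (adjusted p up to 0.294), and that for H2AFZ without any 1 of the 4 arrays (adjusted p = 0.0547 to 0.0853). SET was also lost on its own arrays alone, and H2AFZ without background correction and with the authors' values. Those for CHD9, TDG and HDAC10 were lost in other settings, without the dye term for CHD9 (adjusted p = 0.159), which had the same sign on 3 of 4 arrays. TET2 and TDG each passed with 1 of 3 probes.

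Of 37 oocyte-specific and maternal-effect genes, 0 rose and 13 fell at GV1 (1 and 19 adjusted over the list alone), with a median log2 ratio of −0.33. Their median log2 intensity was 12.1, against 8.76 over all genes, and how brightness bears on these counts was not tested. The list passed camera with its preset correlation (adjusted p = 0.00183) and not with an estimated correlation (adjusted p = 0.909), nor with arrays scaled to equal spread (adjusted p = 0.14). NLRP2, a maternal-effect gene, had a log2 ratio of −1.25, and ZP4, a protein of the zona pellucida, −0.44, a call lost with median centring. Of 45 proteasome subunits 2 rose and 10 fell (4 and 13 adjusted over the list alone), PSMA2 at −1.85 with 4 of 5 probes past the threshold and the assembly chaperone PSMG1 at 0.45. Of 78 nuclear genes of oxidative phosphorylation 5 rose and 8 fell (6 and 8 adjusted over the list alone), with the succinate dehydrogenase subunits SDHA at −0.85 and SDHD at 0.67. Of 68 cytosolic ribosomal protein genes 5 rose and 7 fell (5 and 7 adjusted over the list alone), with RPL22L1 at −1.27 and RPSA at −0.40. Among markers of other cell types, 1 of 22 cumulus and granulosa genes rose and 1 fell, SERPINE2 at 0.45 and the gap junction gene GJA1 at −1.82. Of 13 theca, stroma and endothelium markers 0 rose and 2 fell, NR2F2 at −0.53 and COL4A1 at −0.44, and of 11 blood cell markers 1 fell, FCER1G at −0.12. The 3 marker lists did not pass camera, the smallest of their adjusted p being 0.658. Their median log2 intensities were 8.36, 8.23 and 7.77, below that of all genes, at percentiles 42.4, 39.1 and 17.4. The brightest marker of each list lay above that median, STAR at 14.5, ACTA2 at 11.0 and CD3E at 9.90. The medians thus do not show that other cells were absent. The calls for SERPINE2 (without replicates 1, 3 or 4) and FCER1G (without 2 or 3) were lost when single arrays were left out, with adjusted p = 0.183 and 0.166 without replicate 3. FCER1G, with the same sign on 3 of 4 arrays, was also lost in 5 other settings (adjusted p up to 0.362), and SERPINE2 with median centring and on its own arrays alone. Those for RPSA and PSMG1 were lost with median centring. GJA1 passed with 1 of 2 probes, NR2F2 with 1 of 3 and RPSA with 2 of 3.

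In all, 5539 probes passed at GV1, 2085 higher and 3454 lower, which covered 809 genes higher and 1705 lower, and 354 of the probes changed at least 2-fold. Without replicate 3 the count was 3034, and with median centring in place of loess it was 2400. With arrays scaled to equal spread it was 634, 93 higher and 541 lower, so that the higher share moved from 37.6% to 14.7%.

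**Figure D1:**
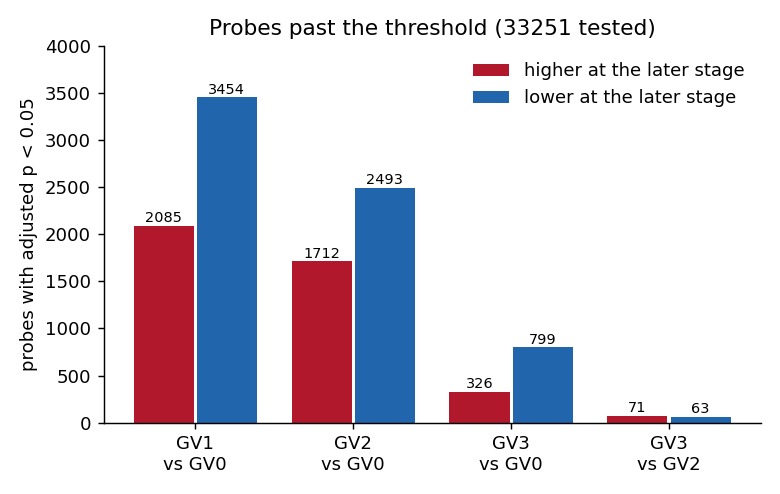
Number of probes with adjusted p under 0.05 in each comparison (y axis), of 33251 tested, with bars for probes higher and lower at the later stage. The count lay at 5539 for GV1 against GV0 and at 134 for GV3 against GV2.

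The comparison of GV2 with GV0 asked the same of the next stage. HIST1H1C was 3.50-fold higher (log2 ratio 1.81 ± 0.18, SE, n = 4, limma adjusted p = 5.8e-05), and NFKBIA, TMPO, SLC35F4 and GALNT13 rose by 1.40, 1.12, 1.26 and 1.06. STAP1, an adaptor protein, rose by 1.21 with 2 of 2 probes past the threshold, CRHBP, which binds corticotropin-releasing hormone, by 1.16, CD3G by 1.06, NUFIP2 by 1.04 and the nucleolar protein gene ESF1 by 1.03. AEBP2 was 6.95-fold lower (log2 ratio −2.80 ± 0.20, SE, n = 4, limma adjusted p = 3.7e-06), and STAMBP, CCDC85A, PTCH1, LRPPRC and CBX3 had log2 ratios of −2.57, −2.52, −2.48, −2.35 and −2.35. ADPRHL2, which removes ADP-ribose from proteins, CYP26A1, PGM3, an enzyme of amino sugar synthesis, and TMBIM6 had log2 ratios of −2.22, −2.21, −2.20 and −2.13. Only 1 probe of the gene passed in that direction for AEBP2 and CBX3 (of 2) and for PTCH1 and TMPO (of 3). Each of these 20 genes had 4 of 4 arrays on the same side, as the rule for naming them required. Each passed in all settings in which it was tested.

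Of 48 histone methyltransferases and demethylases 4 rose and 9 fell at GV2 (5 and 10 adjusted over the list alone), with SETD2 at −1.81 and EED, a core subunit of Polycomb repressive complex, at −1.12, with 1 of its 2 probes past the threshold. Of 36 remodelling complex genes 5 rose and 4 fell (7 and 7 adjusted over the list alone), CHD1L at −0.96 and INO80 at 0.39. Of 24 acetyltransferases and deacetylases 0 rose and 5 fell (1 and 5 adjusted over the list alone), HDAC10 at −0.31 and SIRT2 at −0.41 in 1 of 2 probes. In the condensin and cohesin list 3 rose and 6 fell of 36 (3 and 8 adjusted over the list alone), with STAG3 at −0.88. Of 24 histone chaperones 3 rose and 1 fell (3 and 1 adjusted over the list alone), SET at 0.59 and IPO4 at −0.82. HIST1H1C was the only one of 9 replication-dependent histones to rise and 0 fell (1 and 0 adjusted over the list alone), and H3F3C rose by 0.30 among 7 variants (1 and 0 adjusted over the list alone). In limma 0 of 16 genes of DNA methylation passed. Of 37 oocyte-specific genes 0 rose and 10 fell (0 and 14 adjusted over the list alone), with a median of −0.27 and a camera adjusted p of 0.00183, which with an estimated correlation was an adjusted p of 0.909. NLRP2 had a log2 ratio of −1.15 and TLE6, a member of the subcortical maternal complex, −1.03. NLRP5, of the same complex, had −1.86 (limma adjusted p = 0.033, n = 4), and without replicate 2 it had −1.02 (adjusted p = 0.202); without replicates 1, 3 or 4 its adjusted p was 0.0529 to 0.0595, and it was also lost without background correction and on its own arrays alone (adjusted p up to 0.134). The call for SIRT2 was lost without replicate 3 (adjusted p = 0.0621), that for INO80 with median centring or its own arrays alone, and those for HDAC10 and H3F3C in 2 settings each.

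Of 45 proteasome subunits 3 rose and 7 fell at GV2 (3 and 8 adjusted over the list alone), PSMA2 at −1.81 in 3 of 5 probes and PSMG1 at 0.34. In oxidative phosphorylation 3 rose and 14 fell of 78 (5 and 17 adjusted over the list alone), SDHA at −0.74 and SDHD at 0.67. Of 68 ribosomal protein genes 3 rose and 8 fell (3 and 8 adjusted over the list alone), RPL22L1 at −1.26 and RPL21 at 0.56 in 1 of 4 probes. Among 22 cumulus and granulosa markers 1 rose, SERPINE2 at 0.64, and 1 fell, GJA1 at −1.32 in 1 of 2 probes. Of 13 theca, stroma and endothelium markers 0 rose and 3 fell, with NR2F2 at −0.33 in 1 of 3 probes and COL4A1 at −0.29, and 0 of 11 blood markers passed in limma. The calls for COL4A1 and NR2F2 were lost without replicate 3 (adjusted p = 0.0843 and 0.087), COL4A1 also without replicate 1 and NR2F2 without replicate 4. COL4A1 had the same sign on 3 of 4 arrays and was lost on its own arrays alone (adjusted p = 0.121). Those for SERPINE2, PSMG1, SDHD and RPL21 were lost with median centring, and that for GJA1 on its own arrays alone. At GV2, 4205 probes passed, 1712 higher and 2493 lower, for 779 genes higher and 1165 lower, and 322 changed at least 2-fold. The count was 2760, 2772, 2265 and 2634 without replicates 1, 2, 3 and 4. With median centring 304 were higher and 3382 lower, so that the higher share moved from 40.7% to 8.25%.

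**Figure D2:**
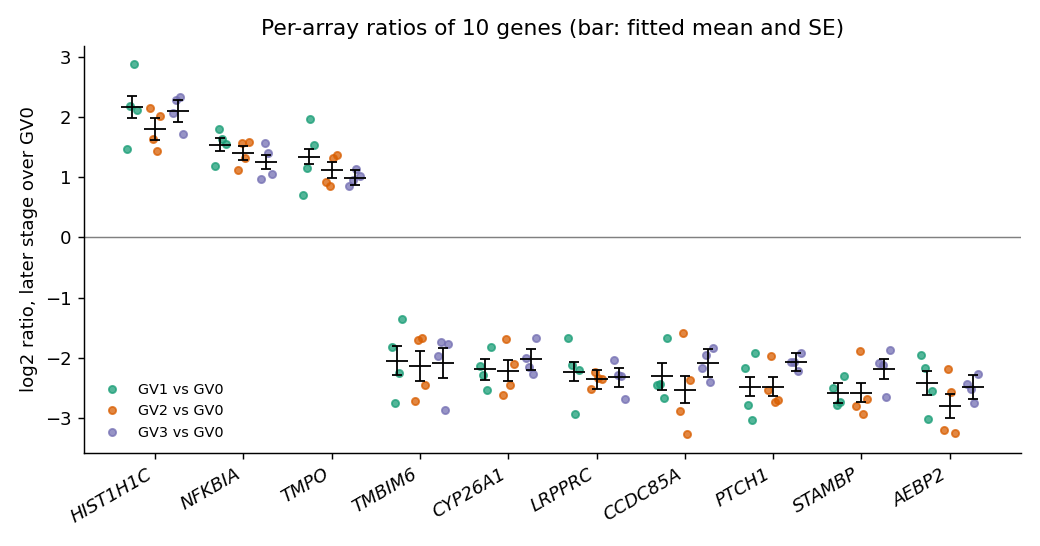
Log2 ratio of the later stage over GV0 (y axis) for the 10 genes among the largest changes of all 3 comparisons with GV0. Points are single arrays (4 per comparison), and bars are the fitted mean with its standard error.

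The comparison of GV3 with GV0 covered the most condensed stage. HIST1H1C was 4.28-fold higher (log2 ratio 2.10 ± 0.18, SE, n = 4, limma adjusted p = 3.2e-05), and NFKBIA and TMPO rose by 1.25 and 0.99. CBX8, a Polycomb protein, rose by 1.49, EIF1AD by 0.91, the Mediator subunit MED20 by 0.78, FAM32A by 0.75, the sulfotransferase CHST4 by 0.75, MBNL2, a splicing regulator, by 0.74 and STXBP3, of vesicle fusion, by 0.68. AEBP2 was 5.60-fold lower (log2 ratio −2.49 ± 0.20, SE, n = 4, limma adjusted p = 1.5e-05), and CBX3, LRPPRC and STAMBP had log2 ratios of −2.41, −2.32 and −2.18. CCDC85A, TMBIM6, PTCH1, CYP26A1, PGM3 and SELS, of the degradation of misfolded proteins, had log2 ratios of −2.08, −2.08, −2.07, −2.02, −1.99 and −1.93. For AEBP2, CBX3, FAM32A and EIF1AD 1 of 2 probes passed in that direction, and for PTCH1, TMPO and MBNL2 1 of 3. The calls for CBX8 and EIF1AD were lost without replicates 3 or 4 (adjusted p = 0.058 and 0.194 without replicate 3), that for FAM32A without replicate 3 (adjusted p = 0.0501), that for CHST4 without replicates 1, 3 or 4 (adjusted p = 0.234 without replicate 3) and that for MED20 without any 1 array (adjusted p = 0.167 without replicate 1). MBNL2, FAM32A, EIF1AD, MED20 and CHST4 did not pass with median centring, nor MED20 and CHST4 on their own arrays alone.

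Of 48 histone methyltransferases and demethylases 2 rose and 6 fell at GV3 (4 and 10 adjusted over the list alone), SETD2 at −1.45 in 2 of 3 probes and EED at −1.25 in 1 of 2. STAG3 had a log2 ratio of −0.77 among 36 condensin and cohesin genes, of which 0 rose and 4 fell (0 and 4 adjusted over the list alone). SET rose by 0.55, the only one of 24 chaperones past the threshold (1 and 0 adjusted over the list alone). HIST1H1C rose among 9 replication-dependent histones, of which 0 fell (1 and 0 adjusted over the list alone), while by limma 0 of 7 variants and 0 of 16 genes of DNA methylation passed. CHD1L at −0.68 was the only one of 36 remodelling genes to fall (0 and 2 adjusted over the list alone), and HAT1 at −0.43 the only one of 24 acetyltransferases and deacetylases (1 and 1 adjusted over the list alone). Of 37 oocyte-specific genes 0 rose and 2 fell, LHX8 at −0.45 in 2 of 3 probes and UCHL1 at −0.38 in 1 of 3 (0 and 4 adjusted over the list alone). PSMA2 at −1.59 in 2 of 5 probes and PSMA1 at −0.51 were among 3 proteasome subunits of 45 that fell, while 0 rose (4 and 4 adjusted over the list alone). Of 68 ribosomal protein genes 1 rose and 3 fell (2 and 3 adjusted over the list alone), RPL22L1 at −1.20 and RPL12 at −0.34, and SDHA at −0.41 was the only one of 78 oxidative phosphorylation genes to fall (0 and 0 adjusted over the list alone). GJA1, at −1.34 in 1 of 2 probes, was the only one of 22 cumulus and granulosa markers past the threshold, with 0 of 13 theca, stroma and endothelium and 0 of 11 blood markers in limma. The calls for HAT1, UCHL1, SDHA and PSMA1 were lost without any 1 of the 4 arrays (highest adjusted p = 0.275, 0.236, 0.234 and 0.227). Those for LHX8 (without replicates 2, 3 or 4, adjusted p up to 0.118), RPL12 (without 1, 2 or 4, up to 0.126), GJA1 (without 2 or 3, up to 0.076) and CHD1L (without 3, 0.0746) were lost too. With median centring HAT1, UCHL1, SDHA, LHX8, RPL12 and CHD1L were lost, and on their own arrays alone HAT1, UCHL1, RPL12 and CHD1L.

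At GV3, 1125 probes passed, 326 higher and 799 lower, for 134 genes higher and 416 lower, and 186 changed at least 2-fold. Without replicates 1, 2, 3 and 4 the count was 660, 602, 465 and 640, and with median centring it was 465. The higher share was 29.0%, against 14.2% with median centring (66 higher, 399 lower) and 39.2% with equal spread (1687 higher, 2616 lower).

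The comparison of GV3 with GV2 set the last stages against each other on 4 arrays. XAB2, a protein of transcription-coupled repair, was 2.22-fold higher at GV3 (log2 ratio 1.15 ± 0.21, SE, n = 4, limma adjusted p = 0.042), and NDUFV1, a subunit of respiratory complex I, rose by 1.08. SEPT1, C12orf10, SYTL3, CCL25, UBE2V1, C25H7orf42, CACNB3 and DHRS7B were higher by 0.96, 0.95, 0.84, 0.83, 0.80, 0.68, 0.61 and 0.61. NIPSNAP3A was 2.05-fold lower (log2 ratio −1.03 ± 0.15, SE, n = 4, limma adjusted p = 0.027), and LRRC17, ELF1, SEC24D, of COPII vesicles, TIFA, SBDS, of ribosome assembly, CSNK1G3, TANK, DUSP11 and TMF1 had log2 ratios of −0.84, −0.62, −0.59, −0.59, −0.57, −0.56, −0.56, −0.56 and −0.52. LHX8 had a log2 ratio of −0.50, INO80 −0.38, H3F3C −0.35, MED10 −0.33 and HDAC10 0.33. Of the probes of a gene 1 of 3 passed in that direction for NIPSNAP3A, ELF1 and SBDS, 1 of 2 for SEPT1, CCL25, CSNK1G3 and MED10, 2 of 5 for C12orf10 and 2 of 3 for LHX8. All 25 calls were lost on the 4 arrays alone and with median centring, and each was lost without at least 3 of the 4 arrays (adjusted p = 0.056 to 0.319).

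In this comparison 1 of 37 oocyte-specific genes fell and 0 rose (7 higher and 1 lower adjusted over the list alone), with a median of 0.14 and a camera adjusted p of 0.00236. Of 78 oxidative phosphorylation genes 1 rose and 0 fell (12 and 2 adjusted over the list alone), with a median of 0.17 and a camera adjusted p of 0.00236. Of 68 ribosomal protein genes 0 passed in limma in either direction (6 and 0 adjusted over the list alone), with a median of 0.15 and a camera adjusted p of 0.00753. With an estimated correlation the adjusted p was 0.909 for each of these 3 lists, and without GV3 against GV2 replicates 1 or 3 only 3 of the 5 list calls over all comparisons passed. In limma 0 of 9 replication-dependent histones and 0 of the 3 marker lists' genes passed. The cumulus and granulosa markers had a median of −0.089 and did not pass camera (adjusted p = 0.0813), though they did with median centring (adjusted p = 0.0127). With an estimated correlation 0 of the 12 marker tests passed. A total of 134 probes passed, 71 higher and 63 lower, and 4403 had an unadjusted p under 0.05. The count was 0, 0, 0 and 32 without replicates 1, 2, 3 and 4. The higher share was 53.0%, against 72.2% with both channels above background (171 higher, 66 lower), 67.3% with array weights (398 and 193), 79.5% at 1.5-fold (35 and 9) and 31.2% without replicate 4 (10 and 22).

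**Figure D3:**
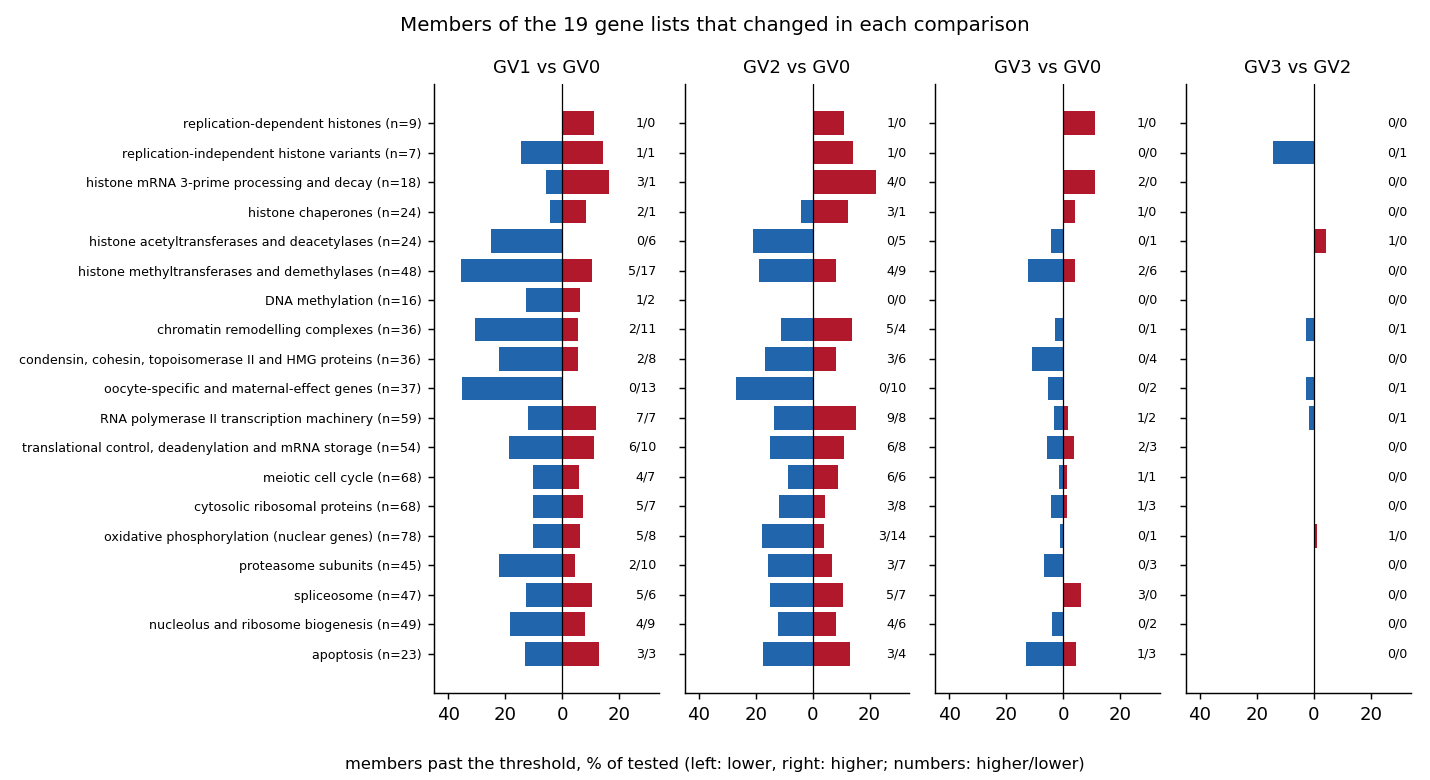
Share of the tested members of each of 19 gene lists that passed the threshold in each comparison (x axis, percent; left lower, right higher at the later stage). Of the oocyte-specific genes 13 of 37 were lower at GV1 and 0 were higher.

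Several genes fixed for reporting did not pass. At GV1, GV2 and GV3 against GV0 the log2 ratio of the oocyte linker histone gene H1FOO was 0.12, 0.25 and 0.12, and that of SLBP, which binds the stem-loop of histone messages, was −0.32, −0.32 and −0.36. GDF9 and BMP15, growth factors secreted by the oocyte, had −0.16, −0.10 and −0.31, and 0.02, 0.24 and 0.27. ZAR1 had −0.11, −0.06 and −0.09, DNMT1 −0.56, −0.41 and −0.20, HDAC1 −0.37, 0.06 and −0.19, and CCNB1 0.16, 0.16 and 0.29. H2AFZ had −0.72 at GV2 and −0.77 at GV3, and NLRP5 −1.33 at GV1 and −0.39 at GV3. Between GV3 and GV2 the largest value among these genes was −0.89 for H2AFZ (limma adjusted p = 0.31), followed by 0.78 for NLRP5 and 0.41 for DNMT1. Taken through GV0, the H2AFZ ratios of −0.72 and −0.77 would give almost no difference between GV3 and GV2. Its direct value is thus not borne out by the other arrays. HDAC1, H1FOO, CCNB1, ZAR1 and GDF9 had log2 ratios of −0.13, −0.12, −0.088, −0.024 and −0.026, and BMP15 and SLBP had 0.077 and 0.023.

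The 3 comparisons with GV0 shared many changes. In all 3, 239 probes were higher and 632 lower, for 102 genes higher and 328 lower. Among these were genes printed in this text for some stages only, such as SUPT4H1, TAF11, NOP58, DDIT3, AURKB and ZCCHC11. EED (−1.08, −1.12 and −1.25 at GV1, GV2 and GV3) and HAT1 (−0.49, −0.46 and −0.43) were others. So were MED20 (0.71, 0.88 and 0.78) and MBNL2 (0.70, 0.85 and 0.74). The log2 ratios correlated across probes at 0.854 for GV1 and GV2, 0.678 for GV1 and GV3 and 0.699 for GV2 and GV3. Unchanged stages simulated against the same GV0 gave 0.498, 0.507 and 0.495, and probes are not independent replicates. The simulation gave GV0 and the other stage equal shares of the variance, with GV0 common to arrays of the same number. Its correlations therefore follow from this setting, and the labels give no such pairing. The covariances were 0.0717, 0.0418 and 0.0418, against 0.00781, 0.00811 and 0.0077 simulated. With arrays of different replicate numbers set against each other the correlations were 0.662 and 0.664, 0.61 and 0.53, and 0.634 and 0.512. That separates the GV0 RNA only if the replicate number marks it, which the labels do not say. GV1 and GV2 had 1081 probes higher in both and 1888 lower in both, where independent lists would share 107 and 259. GV1 and GV3 shared 261 and 683 (20.4 and 83.0 for independent lists), and GV2 and GV3 shared 270 and 689 (16.8 and 59.9). The simulated unchanged stages shared 0 probes in each pair, as unchanged probes are not expected to pass, so what the common GV0 added to these overlaps among real calls is not known from it. By their labels the GV1 and GV2 arrays were of 1 day and the arrays of GV3 against GV0 of another, so the closer agreement of GV1 with GV2 cannot be told apart from a difference between days.

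The difference between GV2 and GV1, taken through GV0, gave 0 probes in limma, with 1412 of 33251 at an unadjusted p under 0.05. Unchanged probes alone would give somewhat more, so this contrast was conservative. Its result does not show that GV1 and GV2 were alike. HIST1H1C, STAMBP, AEBP2 and SETD2 were past the threshold against GV0 at both stages, and none of them passed in this difference. The direct GV3 over GV0 ratio differed from the sum of GV2 over GV0 and GV3 over GV2 at 0 probes in limma, with 62 at an unadjusted p under 0.05. Of 33251 probes, that is far fewer than unchanged probes alone would give. The test was thus conservative, and its result cannot exclude slide or day effects. With a dye effect per comparison the direct ratio differed from the sum at 14 probes, and with arrays of the same replicate number set together at 7. Across probes the direct ratio and the sum correlated at 0.873, and the median absolute difference was 0.05.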

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

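Tests for single arrays standing apart covered 319 sets of 4 arrays, and 16 values stood apart, 5.02%, where chance gives about 5%. The rule of these tests was set beforehand, but which values they cover was settled after results for a narrower and a wider choice of values had been seen. An array stood apart when its gap to the nearest of the other 3 took up most of the range of the 4.

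On the arrays of GV2 against GV0, replicate 2 had 23.3% of probes above the control spots in Cy3, against 78.4% to 85.4% on the others. The control-spot threshold of that array was 606, against 168 to 205, while its median Cy3 intensity of 221 was close to the 229 to 256 of the others. The low share thus came with a raised threshold. On the same array NLRP5 had a log2 ratio of −4.15, with −1.19 to −1.02 on the others, SETD2 had −1.28 (−2.03 to −1.96), GTF2F1 −0.82 (−0.40 to −0.33), AURKB 0.98 (0.38 to 0.43) and RPL22L1 −0.84 (−1.43 to −1.34). Without it the count for GV2 against GV0 was 2772. In that comparison replicate 1 stood apart for TAF11 at −0.81 (−0.54 to −0.51) and VWF at −0.071 (−1.33 to −1.12).

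For GV1 against GV0, CD3G had 1.81 on replicate 4 (0.77 to 0.94 on the others), SNRPF 0.92 on replicate 3 (0.48 to 0.54), H1FOO 0.65 on replicate 2 (−0.12 to −0.02) and SMC4 −0.38 on replicate 2 (−0.55 to −0.53). For GV3 against GV0, FAM32A had 0.34 on replicate 4 (0.84 to 0.92) and RPL9 −0.36 on replicate 1 (−0.79 to −0.73). For GV3 against GV2, NIPSNAP3A had −1.39 on replicate 4 (−0.94 to −0.89) and NLRP5 1.98 on replicate 2 (0.33 to 0.45).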

How the results depend on the processing

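Settings chosen after the data were seen were a dye effect per comparison, plain background subtraction, equal spread, a control-spot threshold at median plus MAD and closure within replicate number. Where a count moved, the cause was not tested. Counts are given for GV1, GV2 and GV3 against GV0 and for GV3 against GV2, with the reported 5539, 4205, 1125 and 134. Without background correction GV1 had 3681, GV3 2681 and GV3 against GV2 230, with background subtraction 3567, 2575 and 261, and with the authors' values 3592, 2588 and 270. With median centring they were 2400, 465 and 0. Probes above background in both channels of every array gave 2607 for GV2 and 237 for GV3 against GV2, with fewer probes tested. Without the dye term GV3 against GV2 had 16, and on its own arrays 0, GV3 against GV0 then 1735. Stage coefficients gave 6699 for GV2, 2768 for GV3 and 2023 for GV3 against GV2. Array weights gave 3138, 7290, 3804 and 591, and a minimum of 1.5-fold 1644, 1441, 498 and 44. A dye effect per comparison gave 8310 for GV1, 1870 for GV3, 1723 for GV3 against GV2, 5 for GV2 against GV1 and 14 for closure, which within replicate number was 7. Equal spread gave 634 for GV1, 4303 for GV3 and 5 for GV3 against GV2. Leaving out 1 array gave 3034 to 5914, 2265 to 2772, 465 to 660 and 0 to 32, 0 for the GV2 and GV1 difference and closure, and 3 to 6 list calls of 5. An offset of 10 and dim probes kept left every count within 1.5 times, and Aquantile leaves ratios as they are. List calls numbered 0 with estimated correlation, 8 with median centring and 13 with fry, 2 of these among the 5. The replicate number as a block gave 5911, 4587, 1212 and 174, 0 and 0. In the 4 direct comparisons it shared 5158, 3934, 1005 and 94 calls with the reported fit. Over all pairs of comparisons with GV0, 7 of 12 pairs of arrays with the same number correlated over 0.1 (−0.138 to 0.315), and 7 fitted their own number best. The dye effect was not removed for these correlations, and by number the dyes ran opposite on the GV3 slides to those of GV1 and GV2. The values thus cannot settle whether arrays pair by number, and the arrays were not treated as paired. In some comparisons 4 of 4 arrays fitted their own number best. GV2 with GV3 against GV2, sign turned, correlated at 0.426 to 0.747. GV1 with GV3 did so at 0.148 to 0.24, and GV3 against GV0 with GV3 against GV2 at 0.112 to 0.243. That is a hint from the data, not from the design, and the dye could contribute to it. CSTF3 at GV2 reversed to −0.072 with median centring. Of 307 gene values 269 were calls, of which median centring kept 161, ended 107 and reversed 1, own arrays ended 65, no dye term 42, no background correction 10, the authors' values 8, an offset of 10 8 and a dye effect per comparison 3. Of 1076 such calls without 1 array, 808 were kept and 268 lost.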

Other observations

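Tests chosen after the result was seen were the loss of the whole transcript, both explanations of the dye orientations and the fit with a dye effect per comparison. Genes of transcription and RNA processing changed in both directions, as did genes at large, with ratios centred on each array by loess. Over all 12664 genes 809 rose and 1705 fell at GV1 against GV0, 779 and 1165 at GV2, and 134 and 416 at GV3. Of 59 genes of the RNA polymerase II machinery 7 rose and 7 fell at GV1 against GV0, 9 and 8 at GV2, and 1 and 2 at GV3 (11 and 10, 11 and 9, and 1 and 3 adjusted over the list alone). TAF2, a subunit of the promoter factor TFIID, rose by 0.62, 0.77 and 0.51, the last call lost with median centring. SUPT4H1, an elongation factor, fell by 1.43 at GV1, and also passed at GV2 (−0.91) and GV3 (−0.89). TAF11 fell by 0.64 at GV3, and also passed at GV1 (−0.32) and GV2 (−0.60), while GTF2F1 fell by 0.47 at GV2. Of 47 spliceosome genes 5 rose and 6 fell at GV1, 5 and 7 at GV2, and 3 and 0 at GV3 (7 and 8, 6 and 7, and 3 and 2 adjusted over the list alone), with CWC22 at 0.56 and PRPF4 at −0.50 at GV1, CDC5L at 0.48 and SNRPD3 at −0.63 at GV2, and CWC22 at 0.39 and CDC5L at 0.28 at GV3. Of 49 nucleolar genes 4 rose and 9 fell, 4 and 6, and 0 and 2 (8 and 13, 6 and 8, and 1 and 3 adjusted over the list alone), and NOP16 had −1.56, −1.37 and −1.15, with POLR1C at −0.42 at GV1, TAF1A at 0.79 at GV2 and NOP58 at −0.76 at GV3. Of 18 genes that process or degrade histone messages 3 rose and 1 fell, 4 and 0, and 2 and 0 (4 and 3, 4 and 0, and 4 and 1 adjusted over the list alone), with LSM10 at −0.60 and CSTF3 at 0.33 at GV1, CASP8AP2 at 0.53 and PAPOLG at 0.28 at GV2, and CSTF3 at 0.30 and PAPOLG at 0.25 at GV3. None of these lists passed camera. With median centring the calls for PRPF4, CDC5L, TAF1A, NOP58, CASP8AP2, CSTF3, PAPOLG and CWC22 at GV3 were lost, and on the 4 arrays alone those for GTF2F1, CASP8AP2, PAPOLG and CDC5L at GV3. Without the dye term those for PAPOLG at both stages and for CSTF3, CDC5L and CWC22 at GV3 were lost. At GV2 the call for PAPOLG was lost without replicate 2 (adjusted p = 0.0706). At GV3 those for PAPOLG and CWC22 were lost without any 1 array (adjusted p up to 0.251 and 0.27), that for CDC5L without replicates 1, 3 or 4 (up to 0.153), and those for NOP58 and CSTF3 without replicates 3 or 4 (up to 0.111 and 0.076). In that direction 1 of 2 probes passed for SUPT4H1 and POLR1C at GV1, and 1 of 3 for NOP16 and CWC22 at GV3.

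Of 54 genes of translational control 6 rose and 10 fell at GV1 against GV0, 6 and 8 at GV2, and 2 and 3 at GV3 (6 and 12, 7 and 11, and 3 and 4 adjusted over the list alone). DDX6, a helicase of stored messages, had −0.75, −0.83 and −0.53, the last call lost without replicate 3 (adjusted p = 0.0548). ZCCHC11, which adds uridine to RNA, had −0.85 at GV1 and −0.57 at GV3, the latter lost without replicates 2, 3 or 4 (adjusted p up to 0.0855), and CNOT6, a deadenylase, 0.61 at GV2. DDX6 passed with 2, 2 and 1 of 3 probes, and ZCCHC11 at GV3 with 1 of 2. Of 68 genes of the meiotic cell cycle 4 rose and 7 fell, 6 and 6, and 1 and 1 (4 and 7, 7 and 6, and 1 and 1 adjusted over the list alone), with CDC20 at −0.70 and WEE1 at −0.17 at GV1, CDC26 at 0.48 and AURKB at 0.55 at GV2, and AURKB at 0.44 and CCNE1 at −0.39 at GV3. The call for CDC20 was lost without replicates 3 or 4 (adjusted p up to 0.107), that for WEE1 without replicates 1, 2 or 4 (up to 0.0822), and those for AURKB and CCNE1 at GV3 without any 1 array (up to 0.0894 and 0.248). With median centring these 4 and CDC26 were lost, and AURKB at GV2 and WEE1 were lost on the 4 arrays alone. WEE1 was also lost without background correction and with the authors' values, and CDC20 and WEE1 had the same sign on only 3 of 4 arrays. AURKB passed with 1 of 3 probes at GV2 and at GV3. Of 23 genes of apoptosis 3 rose and 3 fell, 3 and 4, and 1 and 3 (4 and 3, 3 and 5, and 1 and 4 adjusted over the list alone), with BNIP3 at 0.48 and DDIT3 at −0.58 at GV1, BCL2L2 at 0.58 and DDIT3 at −0.53 at GV2, and BNIP3 at 0.35 and BIRC3 at −0.54 at GV3. The calls for BCL2L2, BIRC3 and BNIP3 at GV3 were lost with median centring, those for BCL2L2 and BNIP3 at GV3 also on the 4 arrays alone, and that for BIRC3 without replicates 3 or 4 (adjusted p up to 0.0527). DDIT3 passed with 2 of 3 probes at GV1 and 1 of 3 at GV2, and BCL2L2 with 1 of 3.

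In the reported fit fewer probes passed at GV3 (1125) than at GV1 (5539) or GV2 (4205) against GV0. Against GV1 this order depended on the setting, as equal spread gave 634 at GV1 and 4303 at GV3, and array weights gave 3138 and 3804. GV3 against GV1, taken through GV0, gave 0 probes in limma, with 3178 at an unadjusted p under 0.05. This difference was taken only in the fit without pairing of arrays. The spread on the GV3 arrays was not larger, as their median SD within dye orientation was 0.55 of that of the GV1 arrays. The fit used 1 pooled spread per probe for all comparisons, so this value cannot bear on the order of the counts. With each comparison fitted on its own arrays the counts were 5200 at GV1, 2930 at GV2 and 1735 at GV3. Compressed ratios on the arrays of GV3 against GV0 may contribute: over 322 probes the direct GV3 change was 0.864 of the summed one (quartiles 0.741 to 0.958). That stays open, because the probes were picked on GV2 against GV0, which inflates the sum. A real return towards GV0 levels was not separated from this, nor was the day of the arrays, which GV1 and GV2 shared and GV3 did not.

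At 96 genes with several probes there were 205 falls of a probe by at least 2-fold over the 3 comparisons with GV0 (median −1.32), while the 362 values of other probes of the same genes had a median of −0.092 (95% interval −0.22 to −0.02), 119 of them also past the threshold and lower. Loss of the whole transcript would move all of them and stays open, since the lower quartile was −0.53 and the other probes could be too dim to show a fall. The 117 values of brighter ones had a median of −0.093 with an interval of −0.52 to 0.08, and −0.52 at GV2 alone, which decides neither. Falls of a part of the transcript, or of its poly(A) tail before amplification, were not tested.

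Ratios differed between the dye orientations, at 13066 probes on the GV1 arrays against 266, 1445 and 1380 for GV2, GV3 and GV3 against GV2. The effect of Cy5 over Cy3 correlated at 0.246 for GV1 and GV2, −0.163 for GV1 and GV3, and 0.152 for GV2 and GV3. With GV3 against GV2 these 3 correlated at 0.322, 0.534 and 0.109. The difference between replicates 1 and 2 and replicates 3 and 4 correlated at 0.246, 0.163 and −0.152 for the first 3 pairs. A dye bias of each probe shared by all slides, or a difference between the GV0 RNA of those replicates, could contribute. For pairs with GV3 the 2 explanations give the same correlation with opposite signs, so a negative value excludes neither. No biological explanation was tested.

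Turning the arrays of a comparison in all 8 ways gives too few splits for a share under 0.05. For GV1 the real count was 5539 and the highest other 3337, with replicates 3 and 4 turned, which follows the dye orientation (1 of 8 as large). For GV3 against GV0 that same turn gave 1144, against 1125 (2 of 8 as large), and a dye effect per comparison gave 1870. For GV2 and for GV3 against GV2 the real counts were 4205 and 134 and the highest other was 0 (1 of 8 each), with 8268 and 4403 probes at an unadjusted p under 0.05 in limma. For GV2 against GV1 the real count was 0 in limma (1412 at an unadjusted p under 0.05), which all 35 of 35 divisions of the 8 arrays must reach (highest other 128), so these say nothing about chance.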
